A study of Homo sapiens with 6 samples.

How the data were processed

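RNA was measured by sequencing in 6 libraries of SU-DHL-8, a cell line from a diffuse large B-cell lymphoma. The line was treated with the solvent DMSO (3 libraries) or with GSK3685032, an inhibitor of the DNA methyltransferase DNMT1 (3 libraries). Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, the second cDNA strand was marked with dUTP and removed, and both ends of the fragments were sequenced on a NovaSeq instrument. Dose and duration of treatment are not given in the sources used here.

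Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR were used, with no role or order stated. The same notes name the mouse build mm10. The deposited gene IDs are human, however: 34105 of 35974 matched GENCODE release 29, and 99.89% of those overlapped their GRCh38 position, with the same 1-based start in 73.3%. Coordinates below are the deposited ones, read as GRCh38.

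For each gene and library the authors deposited an estimated count and an FPKM value. Both come from the authors' own processing and are named in the file headers, which do not define the scaling. The log2 ratio of count to FPKM, corrected for library totals, had a median SD of 0.0133 over libraries (11195 genes over 100 counts). That is what scaling to a fixed length per gene and to library size would give. The counts are whole numbers, but they do not behave as single read pairs. On average 1319.8 genes per library had a count of 4, against 725.8 with a count of 3 and 474.5 with a count of 5, and similar peaks lay at 8 and 12. A count of 4 was therefore taken as about 1 read pair, as coverage-derived counts would give. How counts were made from coverage, and whether strand was used, is not given in the sources used here. Reads from overlapping, antisense or near-identical genes may therefore be split or shared, and multigene families (GAGE, MAGEA, VCX, CTAG, PRAMEF, TRIM49, alpha-globin, histone and ribosomal protein genes) are uncertain member by member.

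Libraries were grouped by their titles. The treatment labels of inhibitor replicates 2 and 3 read GSK3685033 and GSK3685034, the name with its last digit raised, while the series design names GSK3685032 alone. All 3 were kept as 1 group, and results for inhibitor replicate 1 alone were computed as an alternative. No label says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries within a group had identical values, and every pair differed by 3.36 to 7.04 times the variance expected from sampling of read pairs.

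The design had been written for FPKM values with limma, and named edgeR for the case that counts were found. Counts were found, so the main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with filterByExpr, TMM factors (0.981 to 1.02) and Benjamini-Hochberg adjustment over 20783 tested genes, called at an adjusted p of 0.05, two-sided. Standard errors are the log2 fold change divided by the square root of the F statistic. Where all DMSO counts were 0, the fold is a lower bound against a floor of 12 counts over the group, that is 3 read pairs. Genes with 1 to 12 DMSO counts are given by level, without a fold. Bounds and floors cover counting error only.

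Before the data were examined, 31 gene lists were fixed. Each was tested with camera (limma 3.58.1, inter-gene correlation 0.01, log2 CPM with a prior count of 2), adjusted over lists. An estimated correlation and fry were run beside it. Genes were called switched on at an FPKM under 0.1 in every DMSO library and at least 1 in every inhibitor library, and switched off in the mirror case. The rule for named genes was also fixed: DNMT1, DNMT3A, DNMT3B and UHRF1; the 12 largest increases and 12 largest decreases in log2(FPKM + 0.5) among called genes whose groups did not overlap and whose mean FPKM reached 1 in a group; and up to 4 called members per list with the largest change on that scale. Rows without a symbol, small RNAs, unnamed loci, immunoglobulin and T-cell receptor segments, mitochondrial genes, and Y-linked genes with XIST were left out of the 12. A few genes that the rule selects are not reported here. Values per gene are mean FPKM ± SD (n = 3 per group).

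The tests were checked on simulated counts for 20783 genes, with 200 changed genes, the real library sizes and the estimated dispersions. edgeR recovered 20.0% of genes changed 1.25-fold, 30.0% at 1.5-fold, 46.0% at 2-fold and 72.0% at 4-fold. Among genes with a mean count of at least 100 it recovered 91.7% at 2-fold and 100% at 4-fold. Under 100 counts it recovered 3.8% and 26.3%. It called 11 of 20503 unchanged genes. Another 2 lists of 40 genes were shifted 1.5-fold. Far fewer genes were changed in the simulation than were called in the data, which makes the adjusted p stricter. The shares recovered are therefore not those of the real test. camera called both shifted lists and 0 of 30 unshifted ones. Genes were simulated independently of each other, so this cannot show how often camera falsely calls lists of correlated genes.

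Alternatives covered the filter, the scaling, the tool (DESeq2 1.42.0 or limma), pseudocounts, a replicate block, each library left out and other thresholds. Added after the data were seen were limma with trend on log2 FPKM, counts divided by 4, upper-quartile scaling, libraries without ribosomal protein, elongation factor and mitochondrial genes, and inhibitor replicate 1 alone for the switched and detected genes. The quantile, pseudocount and trend alternatives were run with limma on log2 FPKM, since the count model has no pseudocount. In the tests with inhibitor replicate 1 alone the spread comes from the 3 DMSO libraries, and the lone library is assumed to vary like them.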

Results

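Gene expression was measured in SU-DHL-8 cells, a line from a diffuse large B-cell lymphoma, after treatment with DMSO (3 libraries) or with the DNMT1 inhibitor GSK3685032 (3 libraries). The total estimated count per library was 57451935, 75304441 and 66542417 with DMSO and 56708424, 56795603 and 53846028 with the inhibitor. At about 4 counts per read pair, that corresponds to 13461507 to 18826110 pairs. The first principal component of log2 CPM held 89.1% of the variance and separated the groups.

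The comparison asked which transcripts change when DNMT1, the enzyme that copies DNA methylation onto newly replicated strands, is inhibited. DNMT1 itself (ENSG00000130816, GRCh38 chromosome 19, 10133342 to 10231286) fell from 33.0 ± 0.690 to 12.7 ± 0.774 FPKM, a log2 change of -1.38 (SE 0.055, edgeR adjusted p = 5.38e-08). UHRF1 (ENSG00000276043, chromosome 19, 4903080 to 4962154), which brings DNMT1 to hemimethylated DNA, fell from 73.4 ± 0.843 to 50.1 ± 1.504 FPKM (log2 change -0.56, SE 0.042, edgeR adjusted p = 2.44e-06). DNMT3A (ENSG00000119772, chromosome 2, 25227855 to 25342590), a de novo methyltransferase, rose from 0.970 ± 0.0408 to 1.73 ± 0.0714 FPKM (log2 change 0.83, SE 0.077, edgeR adjusted p = 9.92e-06). DNMT3B (ENSG00000088305, chromosome 20, 32762385 to 32809356), the other de novo enzyme, measured 1.17 ± 0.113 and 1.22 ± 0.0957 FPKM and was not called (log2 change 0.06, SE 0.137, edgeR adjusted p = 0.731). Its sign turned without DMSO replicate 2 (-0.01) and under quantile normalization (-0.28, limma adjusted p = 0.0298).

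**Figure D1:**
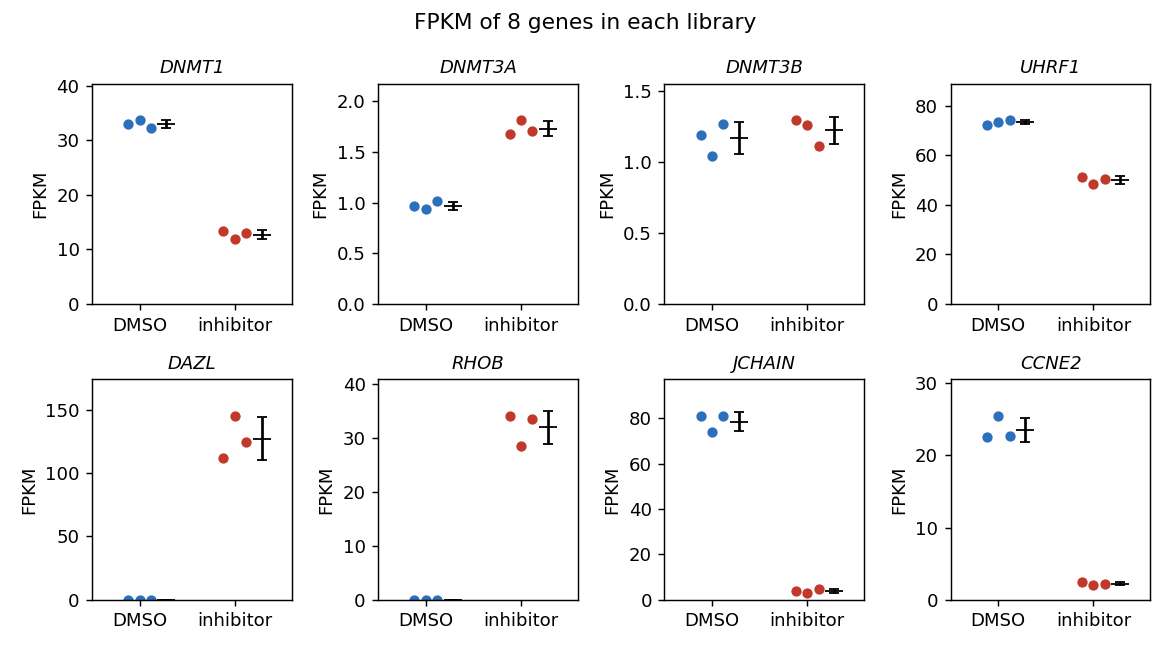
FPKM of 8 genes in the 3 DMSO (blue) and 3 inhibitor (red) libraries, 1 point per library, with the mean and SD in black; each axis starts at 0. DNMT1 lay at 33.0 ± 0.690 FPKM with DMSO and 12.7 ± 0.774 with the inhibitor, and DAZL and RHOB had 0 in every DMSO library.

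Of 20783 genes tested, 7918 (38.1%) were higher and 5672 (27.3%) lower with the inhibitor, and 5266 and 1684 of these changed at least 2-fold. The groups did not overlap in 71.7% of tested genes, where chance gives 10%. Among the higher genes, 1809 had 0 counts in every DMSO library, while 22 of the lower genes had 0 in every inhibitor library. With only genes at an FPKM of at least 1 in at least 3 libraries tested, 4826 were higher and 4414 lower. With limma on log2 FPKM, which changes the test, the scale and the genes tested (14807) together, the balance turned to 5194 higher and 5261 lower without trend and 5260 and 5354 with trend (chosen after the data were seen), and with trend and quantile normalization there were 4853 higher and 5776 lower. Counts divided by 4 gave 6595 higher and 5303 lower of 16200, with 3695 and 1384 at least 2-fold. Upper-quartile scaling moved the median of all tested genes by 0.17 on the log2 scale and gave 9312 higher and 4344 lower, so changes near 0 depend on the scaling.

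**Figure D2:**
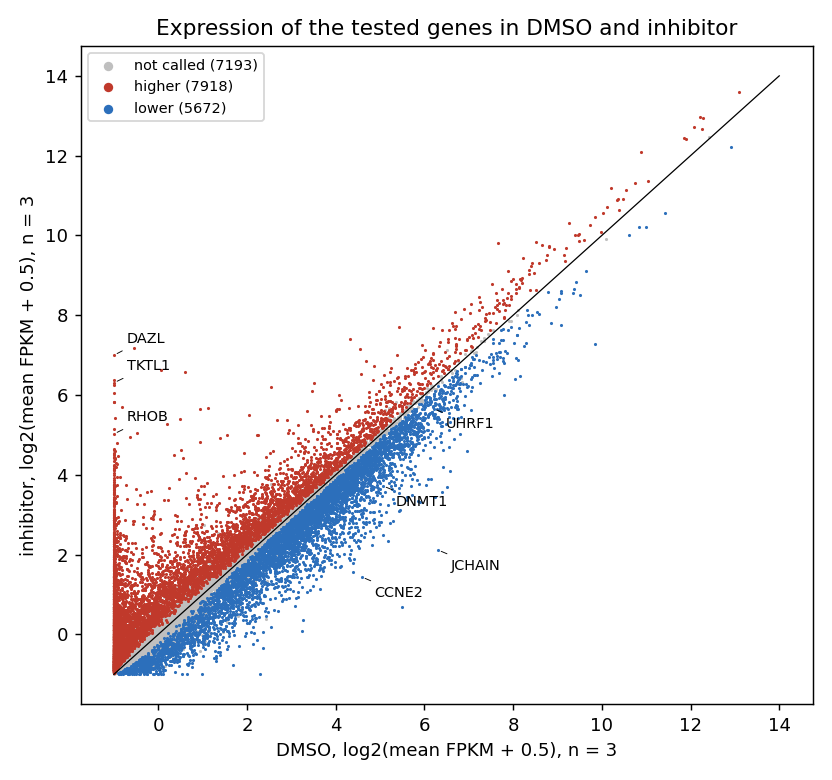
Each point is a tested gene, with log2(mean FPKM + 0.5) in the DMSO libraries on the x axis and in the inhibitor libraries on the y axis (n = 3 each); the line marks equal values. The 7918 higher genes (red) include a column of genes at 0 with DMSO, and the 5672 lower genes (blue) lie below the line.

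The largest increases included germline genes. DAZL (ENSG00000092345, chromosome 3, 16586792 to 16605423), an RNA-binding protein of germ cells, rose from 0 to 127 ± 16.8 FPKM, at least 8002-fold (edgeR adjusted p = 8.94e-09). TKTL1 (chromosome X, 154295795 to 154330350), a transketolase-like gene, reached 78.6 ± 3.57 FPKM, at least 4909-fold higher. MAGEA4 (chromosome X, 151912495 to 151925170), a cancer-testis antigen, reached 75.4 ± 13.8 FPKM, at least 4496-fold higher. PNMA5 (chromosome X, 152988824 to 152994116) reached 66.0 ± 5.92 FPKM, at least 4003-fold higher. The histone H3 variant H3Y1 (chromosome 5, 17654868 to 17655849) reached 82.0 ± 14.9 FPKM, at least 1428-fold higher. RHOB (chromosome 2, 20447074 to 20449440), a small GTPase, reached 32.0 ± 3.06 FPKM, at least 1343-fold higher. GAGE12G and GAGE2A, near-identical X-linked copies whose reads can be shared, reached 56.4 ± 15.2 and 55.8 ± 29.7 FPKM.

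Other large increases started from a few DMSO counts. ASS1, which makes argininosuccinate in arginine synthesis, had 7 counts over the DMSO libraries and 42.8 ± 0.891 FPKM with the inhibitor. CTAG2 had 6 counts and then 27.5 ± 2.47 FPKM. VCX3A, of a family of similar X-linked copies, had 13 DMSO counts and then 51.9 ± 14.9 FPKM. TCL1B, next to the lymphoid oncogene TCL1A, rose from 1.02 ± 0.239 to 94.8 ± 7.98 FPKM (log2 change 6.52, SE 0.136, edgeR adjusted p = 3.36e-09).

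The largest decreases included the B-cell genes JCHAIN and GCSAM and several genes of DNA replication. JCHAIN (ENSG00000132465, chromosome 4, 70655541 to 70666975), the joining chain of polymeric immunoglobulin, fell from 78.5 ± 4.09 to 3.84 ± 0.795 FPKM (log2 change -4.35, SE 0.126, edgeR adjusted p = 1.22e-08). GCSAM, a signalling protein of germinal centre B cells, fell from 84.4 ± 4.50 to 11.3 ± 1.13 FPKM. CCNE2 (chromosome 8, 94879770 to 94896678), a cyclin of S phase entry, fell from 23.6 ± 1.64 to 2.21 ± 0.197 FPKM. PRIM1, the DNA primase subunit, fell from 20.6 ± 1.24 to 2.46 ± 0.289 FPKM. The transcription factors E2F2 and E2F8 fell from 90.5 ± 4.57 to 12.4 ± 1.38 and from 20.4 ± 1.57 to 2.98 ± 0.252 FPKM. TK1, thymidine kinase, fell from 74.6 ± 0.560 to 10.5 ± 2.89 FPKM, and CENPM, a centromere protein, from 35.8 ± 1.48 to 4.60 ± 0.395. ATAD2 fell from 59.5 ± 1.2 to 9.39 ± 1.65 and the receptor GPR19 from 4.67 ± 0.501 to 0.290 ± 0.167 FPKM. APOBEC3B, a cytidine deaminase, fell from 9.09 ± 0.572 to 0.791 ± 0.219 FPKM. The edgeR adjusted p of each of these genes was at most 1.21e-05.

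Genes silent with DMSO and expressed with the inhibitor were counted without a model. By FPKM under 0.1 and at least 1, 522 genes were switched on and 3 switched off. The 3 were IGKJ5, an immunoglobulin segment, and the unnamed genes ENSG00000224365 and ENSG00000273088, named here after their values were seen. Of the 522, 326 had 0 counts in every DMSO library and 60 reached an FPKM of at least 10. The count of genes switched off was 7 without inhibitor replicate 3 and 15 with inhibitor replicate 1 alone, where 610 were switched on.

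More genes were detected per library at an FPKM of at least 1 with the inhibitor, 12313 ± 104 against 11209 ± 51.9 (n = 3 each, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). The difference turned to -123 genes at a threshold of 5 FPKM.

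The 31 gene lists were tested against all other genes with camera, which called 16, 7 higher and 9 lower. With an estimated inter-gene correlation it called 0, and fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes, called 31. The counts adjusted over the list alone equal those below except where given. Across all tested genes 38.1% were higher and 27.3% lower. A gene with 0 counts in every DMSO library could pass the filter only through its inhibitor counts. Its call as higher was therefore nearly fixed in advance, and such members raise the counts of higher genes below.

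Cancer-testis and germline genes rose together. Of 64 tested, 61 were higher and 0 lower, and 41 of 70 members in the table were switched on. Of the 64, 46 had 0 counts throughout a group. DAZL, TKTL1, MAGEA4 and GAGE2A had the largest changes. The median log2 change was 7.30 with genes at 0 set to their bound (camera adjusted p = 4.03e-18, adjusted p = 0.160 with an estimated correlation). The median was 5.41, 3.36 and 2.51 by limma on log2 FPKM with pseudocounts of 0.1, 0.5 and 1, and 2.93 under quantile normalization.

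Imprinted genes, expressed from 1 parental copy, were higher in 28 of 39 and lower in 5 (29 and 5 adjusted over the list alone), with a median log2 change of 1.98 (camera adjusted p = 5.97e-05, adjusted p = 0.150 with an estimated correlation). Of the 39, 11 had 0 counts throughout a group. The noncoding RNA H19 went from 3 DMSO counts to 21.4 ± 3.71 FPKM and MEG3 from 0 to 4.36 ± 0.439 FPKM, at least 1794-fold. PEG10 reached 17.7 ± 0.592 FPKM from 0.0184 ± 0.0193, and MEST 2.90 ± 0.435 from 0.0319 ± 0.0294. The list median was smaller with genes at an FPKM of at least 1 (1.36), with limma on log2 FPKM (1.06, and 1.26 and 0.90 with pseudocounts of 0.1 and 1) and under quantile normalization (0.81).

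HOX and other developmental transcription factors were higher in 38 of 51 and lower in 3 (39 and 3 adjusted over the list alone), at low levels. Of the 51, 26 had 0 counts throughout a group. HOXD13 reached 1.79 ± 0.112 FPKM, NKX6-1 1.10 ± 0.148 and HOXA9 0.790 ± 0.182, all from 0. The median log2 change was 2.80 with bounds (camera adjusted p = 2.55e-05, adjusted p = 0.150 with an estimated correlation). The call ended with limma on log2 FPKM without trend (adjusted p = 0.221), where 15 were tested, 7 higher and 4 lower (median 0.23), and under quantile normalization (adjusted p = 0.659) 4 were higher and 5 lower (median 0.07). It also ended with genes at an FPKM of at least 1 (adjusted p = 0.445).

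Genes often reported as methylated in cancer were higher in 16 of 28 and lower in 8 (17 and 8 adjusted over the list alone), and the list was not called (camera adjusted p = 0.143), but was with inhibitor replicate 1 alone (adjusted p = 0.0324). The balance was lost with limma on log2 FPKM without trend, 8 higher and 7 lower of 18 (median log2 change -0.03), and with genes at an FPKM of at least 1, 6 and 6 of 15 (median 0.05). SFRP5, a secreted WNT antagonist, reached 19.2 ± 1.59 FPKM from 6 DMSO counts. GSTP1, a glutathione transferase, reached 10.1 ± 1.78 FPKM, at least 316-fold higher. The death receptor decoy TNFRSF10D (3.95 ± 0.209 FPKM) and the cell cycle inhibitor CDKN1C (2.21 ± 0.269 FPKM) were also at 0 with DMSO.

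DNA replication genes fell without exception among 52 tested, with a median log2 change of -1.97 (camera adjusted p = 4.91e-24, adjusted p = 0.209 with an estimated correlation). CCNE2, PRIM1, E2F2 and TK1 changed most. Of 60 genes of G2 and mitosis, 59 were lower and 1 higher (median -1.72, camera adjusted p = 1.28e-18, adjusted p = 0.333 with an estimated correlation). CENPM led, followed by the mitotic survival protein BIRC5 (24.5 ± 1.98 to 4.95 ± 1.47 FPKM), the transcription factor FOXM1 (29.8 ± 2.01 to 6.01 ± 1.08) and the kinase PBK (17.7 ± 0.808 to 3.52 ± 1.14).

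DNA repair genes were lower in 39 of 51 and higher in 9 (40 and 10 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 3.07e-09, adjusted p = 0.150 with an estimated correlation). The nuclease EXO1 fell from 22.1 ± 1.09 to 4.12 ± 0.451 FPKM, FANCI from 12.9 ± 0.377 to 2.71 ± 0.503 and XRCC2 from 12.1 ± 0.338 to 2.65 ± 0.446. MYC and ribosome biogenesis genes were lower in 31 of 45 and higher in 4 (median -0.28, camera adjusted p = 3.90e-06, adjusted p = 0.282 with an estimated correlation). MYC fell from 188 ± 3.70 to 111 ± 5.47 FPKM, the nucleolar factor TCOF1 from 17.4 ± 0.416 to 6.98 ± 0.522, PPRC1 from 27.8 ± 0.609 to 14.02 ± 0.860 and PA2G4 from 218 ± 11.01 to 115 ± 2.01. Under quantile normalization that list was not called (adjusted p = 0.0876).

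Nuclear genes of the respiratory chain were lower in 34 of 53 and higher in 5 (35 and 5 adjusted over the list alone; median -0.43, camera adjusted p = 1.80e-07, adjusted p = 0.282 with an estimated correlation). SDHA fell from 44.6 ± 2.62 to 16.3 ± 1.53 FPKM, UQCRC1 from 51.2 ± 1.75 to 22.3 ± 1.08, NDUFB8 from 36.9 ± 1.58 to 16.1 ± 1.35 and NDUFA9 from 10.5 ± 0.153 to 4.40 ± 0.0897.

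Cytosolic ribosomal protein genes went the other way, with 68 of 69 higher and 0 lower (median 0.62, camera adjusted p = 4.75e-15, adjusted p = 0.334 with an estimated correlation). RPS12 rose from 1895 ± 82.3 to 4337 ± 64.7 FPKM, RPL3 from 296 ± 8.08 to 697 ± 25.5, RPS27 from 234 ± 17.5 to 556 ± 19.997 and RPS28 from 30.8 ± 3.45 to 68.1 ± 2.79. They held 4.87% ± 0.154 of counts with DMSO and 7.88% ± 0.162 with the inhibitor. All 13 protein-coding mitochondrial genes were higher (median 0.56, camera adjusted p = 0.00228, adjusted p = 0.441 with an estimated correlation). MT-ND3 rose from 338 ± 9.19 to 599 ± 12.2 FPKM, MT-CO3 from 4785 ± 449 to 8003 ± 341, MT-CO2 from 4999 ± 570 to 7899 ± 15.0 and MT-ATP8 from 4329 ± 945 to 6705 ± 136. Mitochondrial genes held 5.51% ± 0.517 of counts with DMSO and 7.54% ± 0.148 with the inhibitor. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, were higher in 21 of 34 and lower in 0 (median 1.66, camera adjusted p = 0.00205, adjusted p = 0.150 with an estimated correlation). H1-2 rose from 22.7 ± 1.99 to 141 ± 4.79 FPKM, H4C8 from 2.26 ± 0.561 to 15.1 ± 1.02, H3C10 from 1.55 ± 0.323 to 12.7 ± 1.51 and H2BC4 from 0.527 ± 0.257 to 6.93 ± 0.686. The histone median was 1.005 with limma and a pseudocount of 1. With inhibitor replicate 1 alone, the mitochondrial (adjusted p = 0.0684) and histone lists (adjusted p = 0.0512) were not called.

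Chromatin silencing complexes were lower in 23 of 40 and higher in 9 (25 and 10 adjusted over the list alone; median -0.27, camera adjusted p = 0.00191, adjusted p = 0.150 with an estimated correlation). The H3K9 methyltransferases SUV39H1 and SUV39H2 fell from 14.4 ± 0.269 to 3.17 ± 0.632 and from 12.3 ± 1.18 to 4.87 ± 0.310 FPKM. The Polycomb subunits EZH2 and EED fell from 36.3 ± 1.22 to 16.8 ± 0.737 and from 6.53 ± 0.0546 to 3.10 ± 0.320 FPKM. Of 18 genes of the DNA methylation machinery, 9 were lower and 3 higher (median -0.17, camera adjusted p = 0.0440, adjusted p = 0.354 with an estimated correlation). After HELLS, a chromatin remodeller (8.81 ± 0.424 to 2.16 ± 0.520 FPKM), came DNMT1, MBD2 (19.8 ± 0.801 to 9.46 ± 0.184) and TET3 (10.6 ± 0.237 to 5.48 ± 0.358). This last call ended with genes at an FPKM of at least 1 (adjusted p = 0.191), limma on log2 FPKM (0.154, and 0.155 and 0.153 with pseudocounts of 0.1 and 1), quantile normalization (0.264), upper-quartile scaling (0.0754, median 0.00412), counts divided by 4 (0.0711), libraries without abundant genes (0.0508), without inhibitor replicate 2 (0.0543) and with inhibitor replicate 1 alone (0.0813). The chromatin call ended when only genes at an FPKM of at least 1 were tested (adjusted p = 0.0936) and under quantile normalization (adjusted p = 0.492).

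Interferon-stimulated genes were higher in 36 of 60 and lower in 16, and the list was not called against other genes (median 0.45, camera adjusted p = 0.310). The median was 0.12 under quantile normalization. The chemokine CXCL11 went from 5 DMSO counts to 23.9 ± 1.45 FPKM, and LGALS3BP rose from 1.37 ± 0.188 to 11.8 ± 0.627, IFI6 from 1.04 ± 0.630 to 4.26 ± 0.651 and DDX60L from 0.824 ± 0.130 to 3.41 ± 0.275. IFI6 was not called with inhibitor replicate 1 alone (edgeR adjusted p = 0.0508). Genes of nucleic acid sensing, among them adaptors, kinases and deaminases as well as sensors, were lower in 16 of 31 and higher in 7. Adjusted over the list alone, 17 were lower and 8 higher. Their median was -0.41 (camera adjusted p = 0.0194, adjusted p = 0.160 with an estimated correlation). With APOBEC3B, CGAS fell, from 16.7 ± 0.459 to 6.21 ± 1.02 FPKM, while TLR9 rose from 2.37 ± 0.258 to 6.19 ± 0.582 and STING1 from 0 to 0.848 ± 0.190. The call of this sensing list ended with limma on log2 FPKM (camera adjusted p = 0.159, and 0.168 and 0.156 with pseudocounts of 0.1 and 1). It also ended with genes at an FPKM of at least 1 (0.291), quantile normalization (0.237) and counts divided by 4 (0.0661).

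MHC class I genes were lower in 10 of 21 and higher in 7 (camera adjusted p = 0.0795). PSMB8 fell from 31.5 ± 1.42 to 14.9 ± 0.830 FPKM, TAP1 from 42.9 ± 0.514 to 27.1 ± 0.186, TAPBPL from 9.59 ± 0.293 to 5.50 ± 0.420 and ERAP2 from 4.17 ± 0.214 to 2.53 ± 0.245. MHC class II genes were higher in 8 of 18 and lower in 1, and the list was not called (camera adjusted p = 0.219), except under quantile normalization (adjusted p = 0.0485). The invariant chain CD74 rose from 150 ± 6.24 to 350 ± 8.63 FPKM, HLA-DPB1 from 14.9 ± 0.349 to 33.5 ± 2.16 and HLA-DMB from 4.02 ± 0.171 to 8.82 ± 0.681. CIITA, the activator of class II transcription, fell from 30.1 ± 0.421 to 12.9 ± 0.221 FPKM.

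Genes of germinal centre B cells were lower in 14 of 27 and higher in 9 (camera adjusted p = 0.0126, adjusted p = 0.160 with an estimated correlation). Their median was -0.47 while their mean was 0.08 with bounds. GCSAM led, MME (CD10) fell from 4.79 ± 0.394 to 0.998 ± 0.00727 FPKM and MYBL1 from 3.45 ± 0.361 to 0.780 ± 0.150, while MAML3 rose from 0.0472 ± 0.0382 to 1.53 ± 0.188. Plasma cell and activated B-cell genes went both ways, 12 of 29 higher and 12 lower (camera adjusted p = 0.550). JCHAIN fell, as did the kinase PIM1 (36.8 ± 2.67 to 6.47 ± 1.05 FPKM) and TNFRSF17 (2.76 ± 0.292 to 0.498 ± 0.214), while MZB1 rose from 23.3 ± 1.88 to 91.0 ± 1.87. B-cell receptor genes were lower in 17 of 34 and higher in 13 (18 and 13 adjusted over the list alone; median -0.19, mean 0.07, camera adjusted p = 0.134). MS4A1 (CD20) fell from 14.03 ± 0.890 to 3.63 ± 0.779 FPKM and DAPP1 from 7.66 ± 0.445 to 2.36 ± 0.0402, while the kinase FYN rose from 2.54 ± 0.116 to 12.4 ± 0.155 and the phosphatase PTPN6 from 5.12 ± 0.659 to 15.6 ± 1.45.

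Several lists held changes in both directions and were not called. Of 36 p53 targets, 19 were higher and 13 lower (camera adjusted p = 0.894). PLK2 rose from 0 to 1.26 ± 0.234 FPKM and TP53INP1 from 1.33 ± 0.164 to 5.85 ± 0.609, while the repair factor DDB2 fell from 8.13 ± 0.275 to 1.38 ± 0.159. Of 33 BCL2 family and caspase genes, 10 were higher and 13 lower (camera adjusted p = 0.397). BCL2L1, a survival protein, fell from 93.4 ± 6.48 to 34.4 ± 1.8995 FPKM and BIRC3 from 12.6 ± 0.0922 to 2.69 ± 0.307, while CASP1 rose from 1.51 ± 0.190 to 4.69 ± 0.281 and BIK reached 3.92 ± 1.12 from 8 DMSO counts. Of 34 NF-kappaB targets and cytokines, 14 were higher and 14 lower (camera adjusted p = 0.524). BIRC3 fell, while IER3 rose from 1.05 ± 0.412 to 15.9 ± 3.79 FPKM, TNFSF9 from 1.32 ± 0.207 to 10.8 ± 1.07 and CXCL8 from 0.0720 ± 0.0540 to 3.15 ± 0.331.

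Stress response genes were higher in 21 of 35 and lower in 11 (camera adjusted p = 0.219). PHGDH, the entry enzyme of serine synthesis, reached 6.56 ± 0.530 FPKM from 5 DMSO counts, and VLDLR, CHAC1 and CRELD2 rose to 1.56 ± 0.214, 21.1 ± 1.599 and 2.80 ± 0.154. This list was called under quantile normalization (adjusted p = 0.00673) and with genes at an FPKM of at least 1 (adjusted p = 0.0473). Cholesterol synthesis genes were higher in 8 of 24 and lower in 6 (8 and 5 adjusted over the list alone; camera adjusted p = 0.894). ACAT2 and PMVK fell to 11.5 ± 1.78 and 25.1 ± 0.270 FPKM from 30.5 ± 0.809 and 52.1 ± 5.64, while LSS and MVD rose to 6.58 ± 0.441 and 2.79 ± 0.0116 from 2.48 ± 0.107 and 1.09 ± 0.0728. Glycolysis and hypoxia genes were higher in 16 of 33 and lower in 13 (camera adjusted p = 0.894). BNIP3 rose to 2.66 ± 0.427 FPKM, NDRG1 to 1.30 ± 0.0532, the lactate transporter SLC16A3 to 0.952 ± 0.112 and ADM from 0 to 1.02 ± 0.173. For the BCL2 family, NF-kappaB, cholesterol and glycolysis lists camera pointed down, with medians of 0.05, 0.06, 0.09 and 0.05. These lay under the median of 0.14 over all tested genes, and camera compares a list with other genes.

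Of 4 lists of markers of other cell types, 1 was called. Stromal and epithelial markers were higher in 11 of 15 and lower in 2 (median 4.26 with bounds, camera adjusted p = 0.0120, adjusted p = 0.160 with an estimated correlation). VIM rose from 0.914 ± 0.156 to 41.4 ± 2.91 FPKM, KRT18 from 0 to 2.65 ± 0.721 and FN1 from 0.112 ± 0.00467 to 0.846 ± 0.0372, while ACTA2 fell from 2.71 ± 0.298 to 0.568 ± 0.144. Of the 15, 5 had 0 counts throughout a group. The stromal call ended with limma on log2 FPKM (camera adjusted p = 0.107, 5 tested, median 1.14) and under quantile normalization (adjusted p = 0.182, median 0.47). T and NK cell markers were higher in 9 of 13 and lower in 2, and the list was not called (camera adjusted p = 0.0614). It was called with the replicate block (adjusted p = 0.0499), with limma on log2 FPKM (0.0212), with pseudocounts of 0.1 (0.0224) and 1 (0.0216), under quantile normalization (0.0311), without inhibitor replicate 3 (0.0282) and with inhibitor replicate 1 alone (0.0336). ZAP70 rose from 0.0499 ± 0.0193 to 5.12 ± 0.644 FPKM, TRBC2 from 7.09 ± 0.471 to 13.95 ± 1.99, TRAC from 2.42 ± 0.424 to 5.68 ± 0.853 and TRBC1 from 2.05 ± 0.264 to 4.31 ± 0.603. Myeloid markers were higher in 4 of 8 and lower in 0 (camera adjusted p = 0.0795), among them CST3 (0.965 ± 0.147 FPKM), CD33 (0.875 ± 0.0464), TPSAB1 (0.321 ± 0.220) and MPO (0.0763 ± 0.0379). Erythroid and megakaryocyte markers were higher in 4 of 9 and lower in 2 (camera adjusted p = 0.645). The near-identical alpha-globin genes HBA1 and HBA2 rose from 0 to 6.46 ± 1.05 and 7.77 ± 0.821 FPKM and HBE1 to 0.653 ± 0.291, while the transferrin receptor TFRC fell from 18.4 ± 0.939 to 11.9 ± 0.540.

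**Figure D3:**
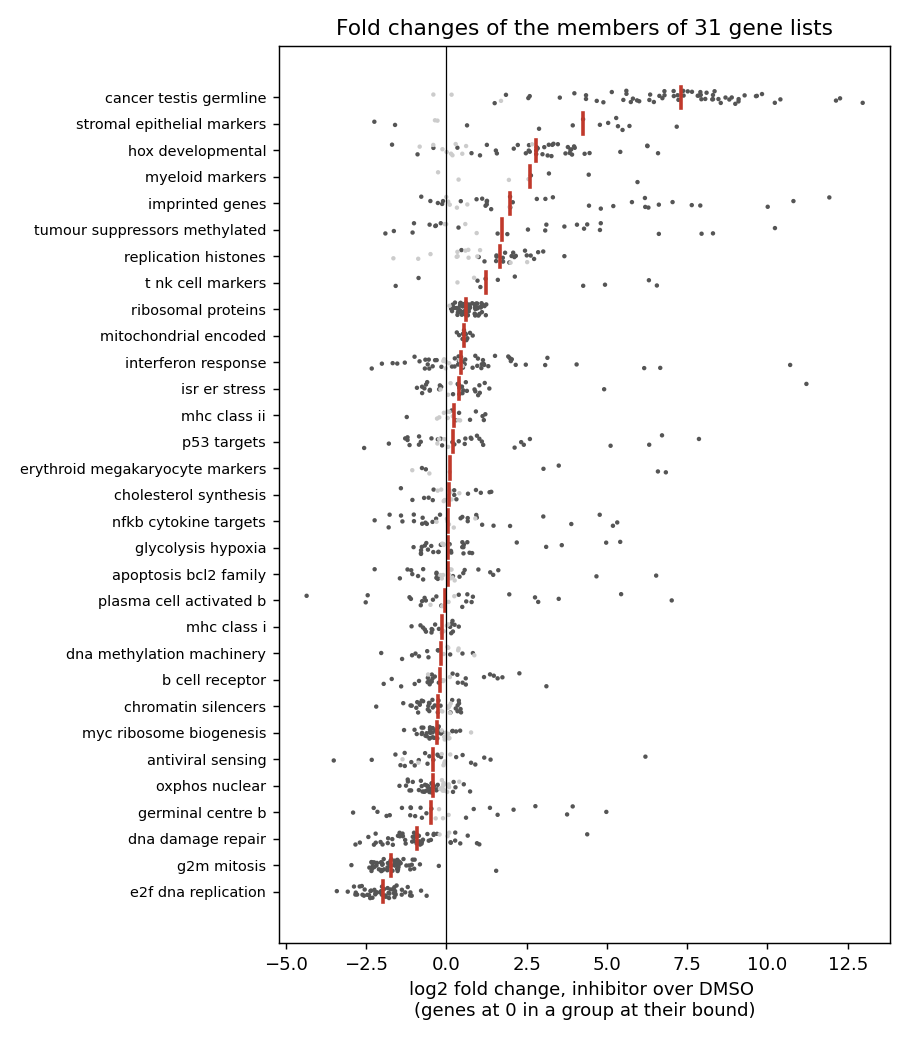
Each point is a tested member of a gene list, placed at its log2 fold change (inhibitor over DMSO, edgeR), with genes at 0 in a group placed at their bound; dark points passed the test and red bars mark the list medians. The lists run from DNA replication (median -1.97) to cancer-testis and germline genes (median 7.30), each with 8 to 69 members.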

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

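Of 137 genes picked by the naming rule, all but DNMT3B kept their direction in every alternative that tested them, and of those called only IFI6 lost its call (with inhibitor replicate 1 alone). Apart from DNMT1, DNMT3A, DNMT3B and UHRF1, these genes were picked as the largest changes among called genes. Their stability was therefore nearly fixed by that choice and does not speak for the other calls. Of the 13590 genes called, 8614 were called in the same direction under quantile normalization and 25 in the opposite one. That setting tested 14807 genes. More genes were switched on than off in every setting. Among genes at an FPKM of at least 1 in at least 3 libraries, 4826 were higher, 1887 at least 2-fold higher and 980 at least 2-fold lower; fewer genes were tested. With limma on log2 FPKM, 5260 were higher and 5354 lower (1992 at least 2-fold, 943 lower at least 2-fold) with trend, chosen after seeing the data, and 5194 and 5261 (1991 and 936) without. A pseudocount of 0.1 gave 5233 higher, 5324 lower and 2495 at least 2-fold higher, and 1 gave 5259, 5356, 1296 and 721 at least 2-fold lower. Quantile normalization gave 4853, 5776 and 1358. The cause of differences among the limma settings was not tested. Counts divided by 4, chosen after seeing the data, gave 6595 higher, 5303 lower, 3695 and 1384 at least 2-fold, and 14 lists. Leaving out each library gave 7481 to 8065 higher, 5263 to 5434 lower, 5103 to 5723 and 1594 to 1735 at least 2-fold, 15 to 17 lists called, 534 to 568 genes switched on, 3 to 7 switched off and a difference of 1070.5 to 1163.5 detected genes. Replicate numbers did not pair the samples (correlations of deviations 0.000, 0.021 and 0.003), and the replicate block gave 7448 higher, 5368 lower, 5013 and 1576 at least 2-fold, and 17 lists, T and NK cell markers being added. Lists called fell from 16 to 0 with an estimated correlation and rose to 31 with fry, which does not compare a list with other genes.

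Genes switched on numbered 954 (7 off) when on meant an FPKM of at least 0.5 and 326 when off meant exactly 0. Switched off genes were 13 when off meant under 0.3, and 15 with inhibitor replicate 1 alone. The difference in detected genes was 3539 at an FPKM of 0.1, -123 at 5, 894 with libraries rescaled to the same total and 984 with inhibitor replicate 1 alone. DNMT3B turned to -0.283 under quantile normalization and -0.0138 without DMSO replicate 2, within a leave-out range of -0.0138 to 0.127. Lists not called in either setting changed direction: cholesterol synthesis with genes at an FPKM of at least 1 (adjusted p = 0.445), pseudocounts 0.1 (0.748) and 1 (0.718), quantile normalization (0.361), limma without and with trend (0.735), upper-quartile scaling (0.805), counts divided by 4 (0.889), inhibitor replicate 1 alone (0.909) and leave-outs (0.877 without DMSO replicate 2 and 0.992 without inhibitor replicate 3, in a range of 0.576 to 0.992). Glycolysis did so in the same order with 0.643, 0.697, 0.686, 0.257, 0.691, 0.805 and 0.889, the BCL2 family under quantile normalization (0.938) and p53 targets with inhibitor replicate 1 alone (0.917). Medians of the MHC class I, plasma cell and DNA methylation lists changed sign with upper-quartile scaling. Among the scalings, those of the erythroid (-0.418) and NF-kappaB (-0.115) lists did so only under quantile normalization. That setting, run with limma on log2 FPKM, also changes the test, the scale and the genes tested, so the scaling alone is not shown to turn them. In the simulation, 2-fold changes were recovered for 3.8% of genes under 100 counts. Far fewer genes were changed there than were called here, so this share cannot be carried over to these data.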

Other observations

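The further gene groups below, the tests of X linkage, depth, another cell line, the first DUX4 list with its comparison to cancer-testis genes and further DUX4 targets outside tandem families, and the settings without abundant genes and with upper-quartile scaling were chosen after the values were seen, as was MTAP with CDKN2A. Clustered protocadherins, cell surface adhesion proteins, were higher in 47 of 49 and lower in 0 (49 and 0 adjusted over the list alone; median log2 change 2.70 with bounds, camera adjusted p = 5.11e-09, adjusted p = 0.0726 with an estimated correlation). PRAMEF genes were higher in 19 of 19 (camera adjusted p = 1.93e-07, adjusted p = 0.134 with an estimated correlation), although near-identical copies share reads, and PNMA genes in 8 of 8 (camera adjusted p = 0.000137, adjusted p = 0.0904 with an estimated correlation). With DMSO, 17 of these protocadherin, 18 of these PRAMEF and 7 of these PNMA genes had 0 counts, so they passed the filter only through their inhibitor counts. Nuclear pore proteins were lower in 21 of 25 (median -0.72, camera adjusted p = 5.94e-09, adjusted p = 0.0904 with an estimated correlation). Mitochondrial ribosomal proteins were lower in 59 of 87 and higher in 6 (median -0.50, camera adjusted p = 3.07e-10, adjusted p = 0.0904 with an estimated correlation), opposite to cytosolic ones. All 12 translation factors tested were higher (camera adjusted p = 7.36e-05, adjusted p = 0.134 with an estimated correlation). ZNF genes were higher in 248 of 557 and lower in 118 (camera adjusted p = 0.0912).

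Of the 522 genes switched on, 94 (18.01%) lay on the X chromosome. They included members of the GAGE, MAGEA and VCX families, whose copies can share reads. XIST, picked after its value was seen, went from 8 DMSO counts to 34.9 ± 4.25 FPKM with the inhibitor. Among genes silent with DMSO, 13.9% of 676 X-linked genes and 2.93% of the others were switched on. The odds ratio was 5.35 (Fisher's exact test, two-sided, p = 1.39e-32, across genes, which are not independent). Genes with 0 counts in every library were absent from the table, so these shares leave them out. MTAP, an enzyme of methionine salvage beside CDKN2A, went from 0 to 2.92 ± 0.253 FPKM, at least 753-fold, while CDKN2A measured 25.9 ± 0.892 and 23.0 ± 1.89 FPKM.

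The 522 genes switched on against 3 off could reflect depth, another cell line or foreign RNA. Total counts argue against depth, since the treated libraries had 0.840 times the DMSO total. The immunoglobulin light chain V gene that led with DMSO held at least 98.2% of light chain V counts in each inhibitor library, as with DMSO. This argues against another B-cell line in place of SU-DHL-8. The share cannot show added RNA from cells that lack light chain transcripts. Whether the XIST counts came from such cells was not tested. Transcripts abundant in spermatocytes and spermatids, 13 of 25 of them in the table, had a median of 0.0291% of the DAZL level, which argues against testis RNA. Loss of DNA methylation at these genes remains a candidate explanation that these data cannot test.

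The real grouping called 13590 genes. Of the 10 splits of the 6 libraries into equal groups, 1 gave as many, the real one, and the highest other called 0; 10 splits are too few for a share under 0.05.

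Replication and mitosis genes fell while ribosomal protein, elongation factor and mitochondrial genes rose. Abundant rising transcripts could push other values down. Without those genes the median of the replication list was -1.96, but TMM factors already correct for such a push, so this refit could move little. Across scalings the median stayed between -1.97 and -1.79. Ribosomal protein genes rose from 4.87% to 7.88% of counts and mitochondrial genes from 5.51% to 7.54%. Shares this small argue against a push of that size. A smaller share of cycling cells, or lower expression in each cell, may account for the fall, and these data do not separate them.

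Known targets of DUX4, a transcription factor of early embryos, were higher with the inhibitor, among them H3Y1 and ZSCAN4 (0.394 ± 0.0396 FPKM). Of 24 silent with DMSO, 22 were higher (Fisher's exact test, one-sided, p = 4.59e-13), and all 8 outside tandem families (100%) were, but both values are fixed by the choice of the list, which was written after its members were seen, so reads shared between near-identical copies stay open. Of 27 further targets written down without their values, 24 were in the table and 22 of these were silent with DMSO. Among the 22, 14 were higher, against 21.6% of other silent genes (Fisher's exact test, one-sided, p = 2.65e-05). Outside tandem families, however, 4 of 9 were (p = 0.109, Fisher's exact test). The table held no gene with 0 counts in every library. Silent genes at 0 with DMSO, here and in the comparison groups, were therefore in it only through their inhibitor counts. DUX4 activity may contribute, but shared reads and loss of methylation at each gene remain open beside it. Silent cancer-testis genes were higher in 55 of 62 (p = 0.516 against the first DUX4 list, Fisher's exact test, one-sided). That list was written after its members were seen, so this comparison cannot decide between the explanations. DUX4 itself had 16 counts over the inhibitor libraries, about 4 read pairs.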
